A study of Mus musculus with 14 samples.

How the data were processed

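Poly(A) RNA of wild-type mouse bone marrow-derived macrophages, which are macrophages grown from bone marrow precursors, was sequenced in 14 libraries. Of these, 6 came from untreated cells, 5 from cells given mast cell supernatant and 3 from cells given mast cell trap supernatant, the treatments lasting 3.5 h. RNA was extracted with a Qiagen RNeasy Plus Micro kit and libraries were made with the Illumina stranded mRNA preparation, per the labels' protocols. The labels place each library in 1 of 3 batches, and every group has at least 1 library in every batch. Nothing in the labels says whether the replicates came from separate cultures or animals, so p-values measure the spread between these samples only, which may be technical.

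The authors deposited raw counts of reads per gene, 1 column per library, as whole numbers that were not normalised. The counts were made with featureCounts 2.0.0 on the GRCm38 build of the mouse genome, per the submitters' processing notes. The aligner, the annotation release, the strand setting and any filter on reads are not given in the sources used here. The table holds 47937 genes by Ensembl identifier. Symbols were found for 47224 of them by identifier in GENCODE release 21 for the mouse and in a RefSeq gene table, and 713 kept the identifier. Coordinates are those of GENCODE release 21 on GRCm38. Total counts ran from 11729073 to 22720419 per library, which sets the precision of genes with few counts: 3 counts over the 6 untreated libraries correspond to 0.0288 CPM, the number of counts per 1e6 counts of a library. Intervals and floors come from counts pooled over a group and cover counting error only, not the spread between libraries. Reads carried no molecular identifiers, so copies of the same molecule may be counted more than once and this error may be understated.

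Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given, which left 13061, libraries were scaled by TMM, and group and batch entered a quasi-likelihood model with robust dispersion over all 14 libraries. Each comparison was tested with edgeR's quasi-likelihood F test, Benjamini-Hochberg adjustment and a false discovery rate of 0.05, and an adjusted p in the text is from this test unless another is named. Standard errors (SE) are those implied by the F statistic. Group means are TMM-normalised CPM with their SD. Log2 differences within a batch are differences of mean log2 CPM with a prior count of 1. Fold changes of genes with 0 counts in all untreated libraries were computed as lower bounds against 3 counts over that group, and ratios of genes with 1 to 3 counts carry an exact 95% binomial interval.

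The 27 gene lists, covering macrophage response and stress programmes, macrophage identity, markers of other cell types and mitochondrially encoded mRNAs, were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. Lists were tested with limma 3.58.1 on voom values: camera with a preset inter-gene correlation of 0.01, camera again with an estimated correlation, and fry, each adjusted over the 27 lists of a comparison. The genes named are, per comparison, up to 10 with the largest rise and 10 with the largest fall among those past the threshold, with a mean of at least 5 CPM and the same sign in each batch, up to 2 members per list and direction, and a fixed panel of 12 genes. Of this panel, Il6 had 23 counts over all libraries and was not tested. Some genes that the rule gives are not reported here. Where other genes are named, the text says so.

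Replicates 1 to 3 carry batch labels 1 to 3 in every group, so these numbers mark a shared batch. After removal of group means, the 9 pairs of libraries with the same number correlated at 0.298 to 0.71 over genes and pairs with different numbers at -0.592 to 0.173, and each of the 9 libraries correlated best with its own number. A fit of these 9 libraries with the number as a block was therefore run beside the model above. Within them the block is the same term as batch, so this fit differs from that model only in using fewer libraries. No 2 libraries held identical counts, and in the 28 pairs within groups the chi-square per degree of freedom was at least 1.82. None was therefore taken as a library deposited more than once. The value ran from 1.82 to 15.2 for pairs in the same batch and from 31.8 to 81.9 for other pairs. Libraries of a batch may thus be technical replicates, and n counts libraries.

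The tests were tried on simulated counts made from the real libraries with 200 changed genes. The changes were set on genes with a mean of at least 1 CPM and were alike in every batch. The shares found therefore do not cover responses that differ between batches. For trap supernatant against untreated (12836 genes), edgeR called 65.7% of the genes changed 1.5-fold, 89.6% of those changed 2-fold and 97% of those changed 4-fold, and 4% of its calls were false. For mast cell supernatant against untreated (12854 genes) these shares were 71.6%, 89.6% and 100%, with 5.43% false. For trap against mast cell supernatant (12864 genes) they were 70.1%, 92.5% and 100%, with 5.41% false. Alternatives tried were DESeq2 1.42.0, limma-voom, another scaling, other filters, models without batch or with the replicate block, only the groups compared, stricter thresholds, and leaving out each library or batch. A model with 9 group-by-batch means, counts without genes nearly absent from untreated cells, list tests in the 8 treated libraries or with the replicate block, and folds of mast cell transcripts without the library that held most of their counts were added after seeing the data. Other splits of the libraries into groups of the same sizes were counted, up to 100 per comparison.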

Results

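Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages that were left untreated (n = 6) or given for 3.5 h the supernatant of mast cells (n = 5) or of mast cell traps (n = 3). The labels call the latter mast cell intracellular traps, and the series title ties them to the trapping of neutrophils by mast cells and to the relay of inflammatory signals. Total counts were 13455686 to 22720419 in untreated libraries, 11729073 to 16123421 with mast cell supernatant and 12414738 to 16491536 with trap supernatant. Mitochondrially encoded mRNAs took 1.19% to 1.6% of the counts. The first principal component held 34% of the variance; batch accounted for 97.8% of it and group for 1.34%. On the second component, with 22% of the variance, batch accounted for 48% and group for 39.6%. Values within batches are therefore given beside many of the pooled ones; every gene named below as risen or fallen had the same sign in each batch.

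Libraries of macrophages given mast cell supernatant contained transcripts of mast cell granule proteins that were almost absent from untreated ones. Itgb3, which encodes integrin beta 3, fell by 1.45 ± 0.1 on the log2 scale (SE; adjusted p = 5.57e-07), from 13 ± 3.56 CPM (SD, n = 6) in untreated libraries to 5.1 ± 1.43 (n = 5). Pdgfa, a growth factor gene, fell by 1.31 ± 0.09 (adjusted p = 1.59e-06), from 115 ± 20.2 to 45.3 ± 3.72 CPM. Il10, the gene of the anti-inflammatory cytokine interleukin-10, rose 3.97-fold, from 4.28 ± 2.51 to 15.3 ± 5.76 CPM (adjusted p = 0.0113). In all, 625 of 13061 genes passed, 283 higher and 342 lower, and 621 of them had the same sign in all 3 batches. At least 2-fold changes were found in 94, of which 64 were higher and 30 lower. Of the genes that rose, 38 averaged under 0.1 CPM in untreated libraries.

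The largest rises belonged to mast cell genes. Mcpt4, a chymase gene (ENSMUSG00000061068, chromosome 14, 56059629 to 56062313), and Tpsb2, a tryptase gene (ENSMUSG00000033825, chromosome 17, 25366305 to 25369098), had 0 counts in all 6 untreated libraries and were at least 4150-fold and 3700-fold higher with mast cell supernatant (adjusted p = 0.0429 and 0.0391). Cma1, another chymase gene (ENSMUSG00000022225, chromosome 14, 55941451 to 55944675), had 1 count over the untreated group, a ratio of 10500 (95% interval 1880 to 415000; adjusted p = 0.000624). Cpa3, the mast cell carboxypeptidase gene (ENSMUSG00000001865, chromosome 3, 20215620 to 20242181), had 2 counts and a ratio of 4050 (1120 to 33500; adjusted p = 0.000942). Rises were also called for Slc18a2, the vesicular monoamine transporter gene, with 2 untreated counts and a ratio of 373 (103 to 3090), and for Kit, the stem cell factor receptor gene, at log2 6.6 ± 0.97. By batch the log2 values were 2.59, 8.31 and 5.78 for Slc18a2 and 3.82, 8.72 and 4.92 for Kit. Mast cell supernatant replicate 2 held most of these counts. In a check added after seeing the data, without it the bounds became 1390 for Mcpt4 and 1330 for Tpsb2, and the ratios 3730 for Cma1 (668 to 147000), 1430 for Cpa3 (395 to 11800) and 109 for Slc18a2 (29.4 to 914). Over single libraries the bound of Mcpt4 ran from 569 to 11600. Il1rl1, which encodes the interleukin-33 receptor, and Hdc, which encodes the enzyme that makes histamine, rose by 4.28 ± 0.93 (1.8, 6.13 and 4.59 by batch) and 2.98 ± 0.58 (3.06, 4.65 and 1.32). Of the 22 measured mast cell markers, 13 rose and 0 fell; adjusted over the list alone, 18 rose and 1 fell. The list was higher than other genes by camera (adjusted p = 7.24e-13), and adjusted p = 0.524 with an estimated correlation. Its median log2 fold change was 7.16 as fitted and 6.59 with genes at 0 set to their lower bound. Its medians by batch were 2.44, 7.48 and 4.76. Of the 22, 4 are expressed at 1 CPM or more by untreated macrophages and 2, Hdc and Il1rl1, are also in the cAMP/CREB list. Reads of the related chymase and tryptase genes could be divided among them in counting, so values of single family members are uncertain.

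**Figure D1:**
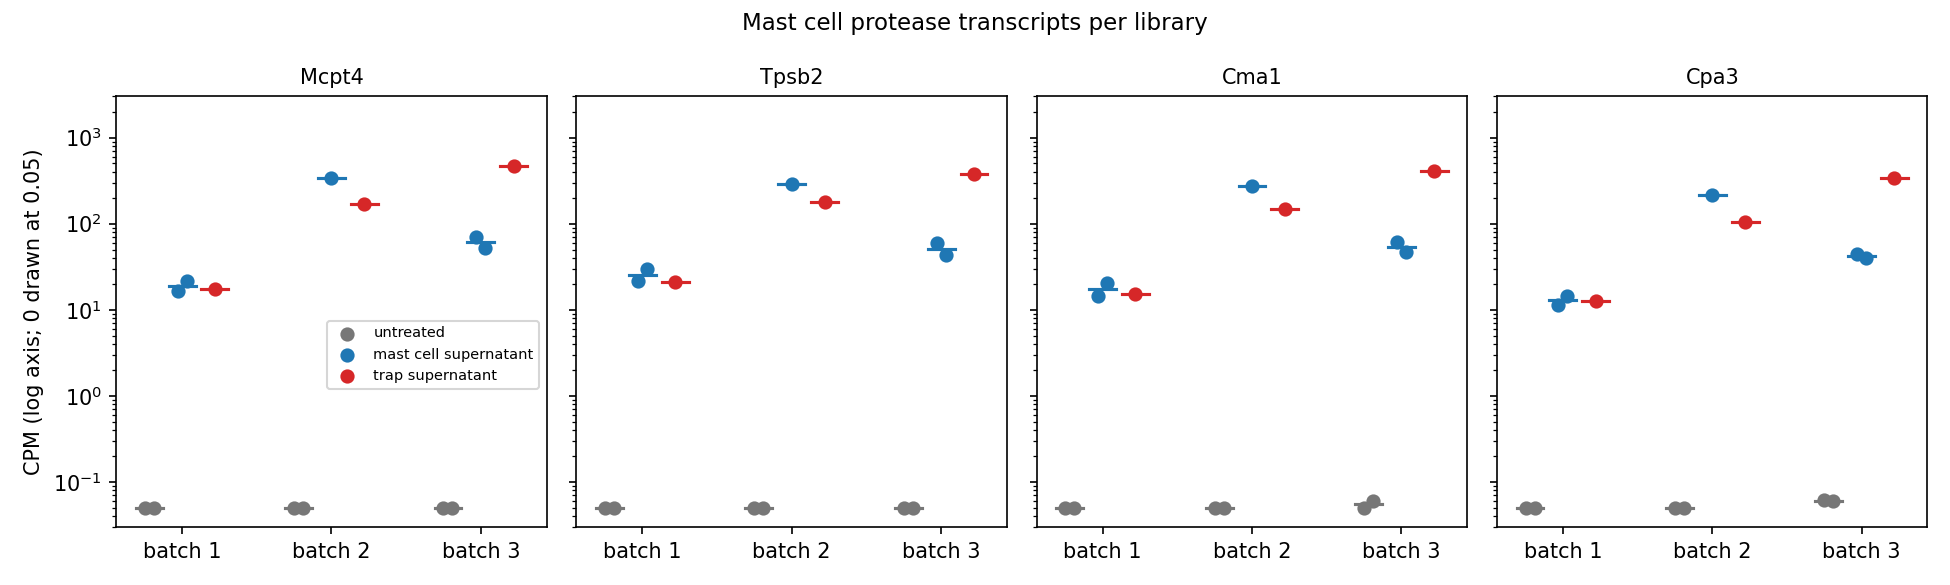
CPM of Mcpt4, Tpsb2, Cma1 and Cpa3 in each library (points) by batch, with short bars for the mean of a group in a batch; the vertical axis is logarithmic and values of 0 are drawn at 0.05. Every treated library lies above every untreated one, and with trap supernatant Cpa3 ran from 12.6 CPM in batch 1 to 340 CPM in batch 3.

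The level of these transcripts varied between treated libraries. Cpa3 was at 11.5 and 14.5 CPM in the batch 1 libraries with mast cell supernatant, at 214 CPM in the single library of batch 2, and at 44 and 39.6 CPM in batch 3. With trap supernatant it was at 12.6, 105 and 340 CPM in batches 1, 2 and 3. Mast cell transcripts thus moved with treatment and differed by batch, beside every gene group described here.

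The largest falls were in genes of varied function. Rab11fip4, which encodes a Rab11 effector, fell by 2.48 ± 0.22 (adjusted p = 4.2e-05), and Usp2, a deubiquitinase gene, fell by 2.01 ± 0.18 (adjusted p = 5.33e-06). Spsb1, a ubiquitin ligase adaptor gene (ENSMUSG00000039911, chromosome 4, 149896283 to 149955043), had the smallest adjusted p, 2.13e-07, and fell by 1.66 ± 0.1, with log2 changes of -1.42, -1.71 and -1.77 in batches 1, 2 and 3. Cx3cr1, the fractalkine receptor gene, fell by 1.43 ± 0.12, from 113 ± 22.8 to 39.7 ± 12.7 CPM. Further falls were those of Atp2b4, a plasma membrane calcium pump (-1.37 ± 0.19; -0.8, -1.33 and -2.05 by batch), Pald1 (-1.34 ± 0.17), Cspg4, the proteoglycan NG2 (-1.25 ± 0.12), and Hivep3, a zinc finger protein (-1.2 ± 0.28; -0.29, -1.14 and -2.17 by batch). Cass4, which encodes an adhesion scaffold protein of the Cas family (ENSMUSG00000074570, chromosome 2, 172393794 to 172433757), rose by 1.5 ± 0.12 (adjusted p = 2.02e-06; 1.29, 1.38 and 1.89 by batch).

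Within the fixed lists, genes of macrophage identity moved both ways with mast cell supernatant. Of 22 measured, 4 rose and 3 fell (5 and 4 adjusted over the list alone): Maf, a macrophage transcription factor gene, rose by 0.95 ± 0.16 and Tlr4, the lipopolysaccharide receptor gene, by 0.45 ± 0.09, while Cx3cr1 and Mertk, a receptor for apoptotic cells, fell, Mertk by 0.9 ± 0.15. Camera gave adjusted p = 0.0673 for this list, and adjusted p = 0.602 with an estimated correlation. Among LXR targets and efferocytosis genes, 0 of 21 rose and 4 fell, Itgb3 and Mertk the most (1 and 6 adjusted over the list alone; camera, lower, adjusted p = 0.0141, and adjusted p = 0.479 with an estimated correlation; 0.0602 with the replicate block; medians of -0.03, -0.13 and -0.09 by batch). In the IL-10/STAT3 list of 16, 2 rose, Il10 among them, and Tnfrsf1b, a TNF receptor gene (-0.67 ± 0.13), and Sbno2 (-0.39 ± 0.04) fell, with the same counts adjusted over the list alone (camera adjusted p = 0.885, and adjusted p = 0.947 with an estimated correlation). In the cAMP/CREB list of 20, 4 rose, Il1rl1, Hdc and Il10 among them, and 0 fell (6 and 1 adjusted over the list alone; camera, higher, adjusted p = 3.64e-06, and adjusted p = 0.524 with an estimated correlation). The medians of this list were 1.12, 0.57 and -0.2 by batch. Of the 4 that rose, Il1rl1 and Hdc are also in the mast cell list, and the cAMP/CREB list was not tested without them. Of 16 chemokines measured, Ccl6 rose (0.38 ± 0.05) and Cxcl16 fell (-0.58 ± 0.11), also adjusted over the list alone.

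With mast cell supernatant, Cxcl1, Tnf, Il1b, Cxcl2, Ccl2 and Ptgs2, inflammatory genes of the fixed panel, had positive values in batches 1 and 2 and negative ones in batch 3. The log2 difference of Cxcl1, a neutrophil chemokine gene, was 4.52 in batch 1, 2.34 in batch 2 and -1.35 in batch 3, and the pooled value of 1.68 ± 0.96 did not pass (adjusted p = 0.38). Tnf, which encodes tumour necrosis factor, had 2.34, 0.66 and -0.86 (pooled 0.65 ± 0.5; adjusted p = 0.531), and Il1b, which encodes interleukin-1 beta, 3.57, 1.57 and -0.46 (pooled 1.89 ± 0.6; adjusted p = 0.118). Values of the same form were found for Cxcl2 (3.64, 2.15 and -1.55), Ccl2 (2.77, 2.63 and -1.92) and Ptgs2, the inducible cyclooxygenase gene (3.94, 2.5 and -0.6). Il10 was higher in each batch, by 3.02, 1.96 and 1.44. Of 26 genes of the NF-kB list, 0 passed by edgeR, over all genes or adjusted over the list alone, with 7 at an unadjusted p under 0.05, 3 past by DESeq2 and 2 by limma-voom (camera adjusted p = 0.562, and adjusted p = 0.947 with an estimated correlation). The list's median was 0.62, 0.06 and -0.62 by batch. The chemokine list was higher by camera (adjusted p = 0.00613, and adjusted p = 0.602 with an estimated correlation), with medians of 0.92, 0.39 and -1.09; its adjusted p was 0.0503 without mast cell supernatant replicate 4. Of 30 immediate early genes, 1 rose, Klf2 (1.12 ± 0.17), also adjusted over the list alone, and the list was higher by camera (adjusted p = 1.26e-06, and adjusted p = 0.524 with an estimated correlation), with medians of 1.23, 0.17 and -0.45.

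**Figure D2:**
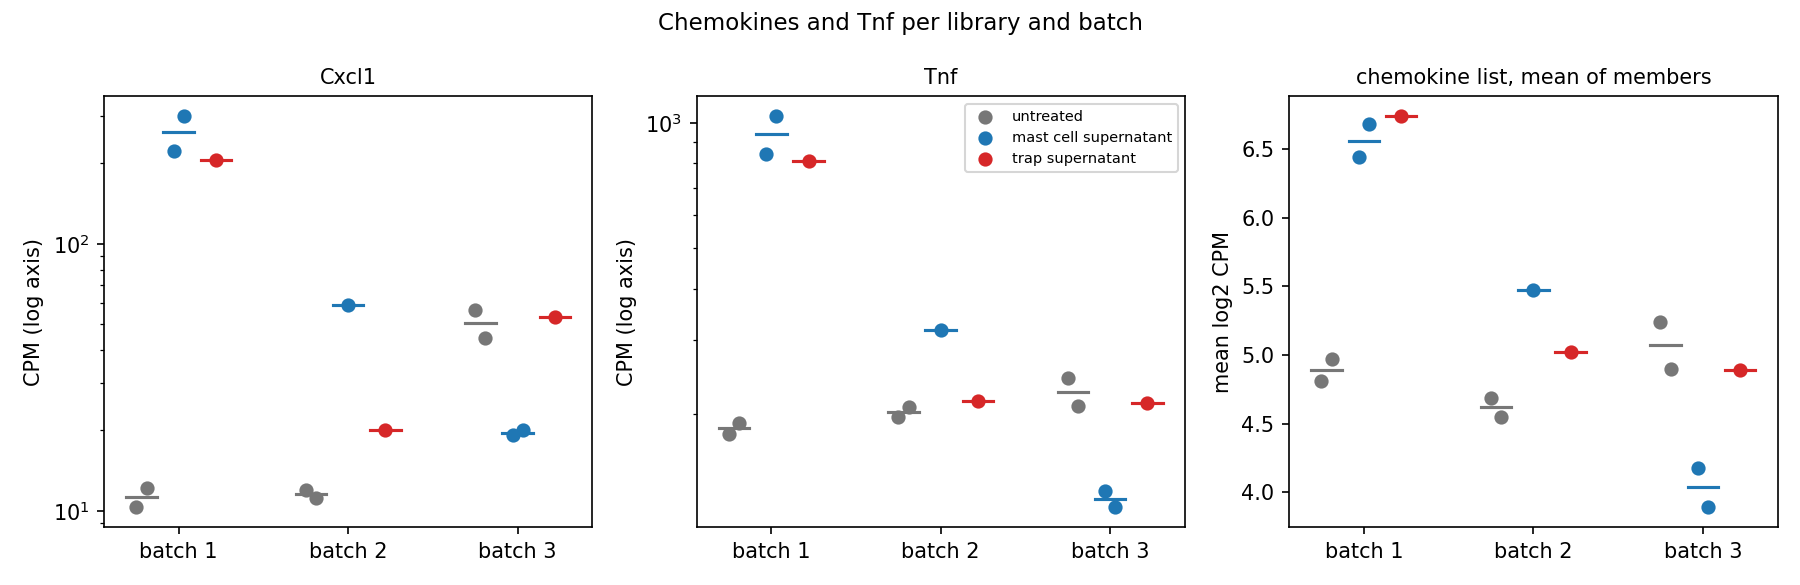
CPM of Cxcl1 and Tnf (logarithmic axes) and the mean log2 CPM of the measured chemokines, for each library (points) by batch, with short bars for the mean of a group in a batch. Cxcl1 was at 222 and 301 CPM with mast cell supernatant in batch 1, against 10.3 and 12.2 CPM untreated, and at 19.2 and 20 CPM in batch 3, against 56.4 and 44.5 CPM untreated.

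For this comparison the count of 625 fell to 62 without the batch term and to 231 without batch 2. With the replicate block (9 libraries, where it is the same term as batch) 84 genes passed, and of the 39 named genes past the threshold 16 passed again. The other 23, the mast cell genes and Il10 among them, had adjusted p from 0.0514 to 0.546 in this smaller fit. When each library was left out in turn, Mcpt4 and Tpsb2 lost their calls in 12 of the fits, Hivep3 in 11 and Il1rl1 in 8. Cma1, Slc18a2 and Hdc lost theirs in 1 fit each: without untreated replicate 6 (adjusted p = 0.0627), untreated replicate 4 (0.111) and untreated replicate 2 (0.052).

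Libraries of macrophages given trap supernatant also contained mast cell transcripts. Metrnl, which encodes the secreted protein meteorin-like (ENSMUSG00000039208, chromosome 11, 121701544 to 121716306), rose 1.78-fold, from 241 ± 49.1 CPM (SD, n = 6) to 428 ± 73.4 (n = 3), by log2 0.83 ± 0.07 (adjusted p = 1.64e-05), with 0.77, 0.91 and 0.82 in the 3 batches. Pdgfa (ENSMUSG00000025856, chromosome 5, 138976014 to 138997370) fell by 1.13 ± 0.11, from 115 ± 20.2 to 52.3 ± 1.76 CPM (adjusted p = 9.91e-05), and Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879) fell by 1.07 ± 0.14, from 113 ± 22.8 to 57.4 ± 34 CPM (adjusted p = 0.00253). Of 13061 genes, 224 passed, 120 higher and 104 lower; 70 changed at least 2-fold (51 higher, 19 lower) and 219 had the same sign in all 3 batches. Of the genes that rose, 37 averaged under 0.1 CPM in untreated libraries.

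Mast cell transcripts again had the largest rises. Cma1 reached a ratio of 19100 (95% interval 3420 to 753000; adjusted p = 0.000976) and Cpa3 one of 7500 (2070 to 61900; adjusted p = 0.00122). Slc18a2 reached 801 (221 to 6630; adjusted p = 0.00467), and Kit, Il1rl1 and Hdc rose by log2 7.81 ± 0.98, 5.36 ± 0.98 and 3.41 ± 0.61. By batch the values were 3.26, 7.58 and 9.05 for Slc18a2, 3.75, 7.75 and 8.13 for Kit, 1.84, 4.94 and 7.58 for Il1rl1, and 2.54, 3.75 and 3.57 for Hdc. Mcpt4 and Tpsb2, at least 7300-fold and 6530-fold higher, missed the threshold (adjusted p = 0.0673 and 0.0618). Without trap replicate 3, which held most of these counts, the bounds became 3670 for Mcpt4 and 3850 for Tpsb2, and the ratios 9480 for Cma1 (1700 to 374000), 3420 for Cpa3 (945 to 28200) and 397 for Slc18a2 (109 to 3300). Over single libraries the bound of Mcpt4 ran from 607 to 16400. Of the 22 markers 11 rose and 0 fell (19 and 0 adjusted over the list alone; camera adjusted p = 9.12e-23, and adjusted p = 0.238 with an estimated correlation), with a median log2 fold change of 8.49 as fitted and 7.7 with lower bounds, and medians of 2.87, 6.75 and 7.86 by batch. Markers of neutrophils, the other cells named with the traps, did not pass: 0 of 21 by edgeR, 1 at an unadjusted p under 0.05, and 0 by DESeq2 and limma-voom (camera adjusted p = 0.468). S100a8, an abundant neutrophil transcript, was at 20.2 ± 10.6 CPM with trap supernatant and 22 ± 10.6 CPM untreated.

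Apart from mast cell transcripts, the rises included Cass4 (1.31 ± 0.14; adjusted p = 0.000104) and Maf (0.86 ± 0.18; adjusted p = 0.0478). Falls were found for Rab11fip4 (-1.46 ± 0.23), Itgb3 (ENSMUSG00000020689, chromosome 11, 104608000 to 104670476; -1.23 ± 0.12; adjusted p = 7.71e-05), Atp2b4 (-1.2 ± 0.22), Cspg4 (-1.19 ± 0.14), Spsb1 (-1.17 ± 0.11; adjusted p = 5.72e-05), Usp2 (-1.15 ± 0.19) and Pald1 (-1.02 ± 0.19). In the macrophage identity list of 22, Maf and Tlr4 (0.6 ± 0.1) rose and Cx3cr1 and Mertk (-0.83 ± 0.17) fell (4 and 2 adjusted over the list alone; camera, higher, adjusted p = 0.0463, not past with an estimated correlation; medians of 0.04, 0.08 and -0.01 by batch). Among 21 LXR targets and efferocytosis genes, Cd36, a scavenger receptor gene (0.23 ± 0.05), rose and Itgb3 and Mertk fell (1 and 2 adjusted over the list alone; camera, lower, adjusted p = 0.0145, and adjusted p = 0.286 with an estimated correlation; 0.0794 with the replicate block; medians of -0.05, -0.04 and -0.14 by batch). In the IL-10/STAT3 list of 16, 1 rose and 1 fell, the latter Sbno2 (-0.25 ± 0.05) (2 and 2 adjusted over the list alone; camera adjusted p = 0.189, and adjusted p = 0.787 with an estimated correlation). In the cAMP/CREB list of 20, Il1rl1 and Hdc rose and 0 fell (4 and 0 adjusted over the list alone; camera, higher, adjusted p = 5.24e-07, and adjusted p = 0.413 with an estimated correlation). The medians of this list were 0.97, 0.23 and 0.09 by batch. Il1rl1 and Hdc, its only members past the threshold, are also in the mast cell list, and it was not tested without them.

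The inflammatory panel again differed by batch. Cxcl1 had log2 differences of 4.19, 0.78 and 0.09 in batches 1, 2 and 3 (pooled 1.34 ± 1; adjusted p = 0.647) and Tnf 2.14, 0.09 and -0.09 (pooled 0.58 ± 0.55; adjusted p = 0.745). Il1b had 2.85, 0.96 and 0.33, Cxcl2 3.31, 0.83 and 0.1, Ccl2 2.9, 0.35 and -0.19, and Ptgs2 3.18, 0.79 and 0.57. Il10 was higher in each batch, by 3.14, 0.7 and 1.32, without passing (1.64 ± 0.41; adjusted p = 0.0949). Of 16 chemokines, Ccl6 rose (0.44 ± 0.05; adjusted p = 0.000339) and 0 fell (3 and 2 adjusted over the list alone; camera, higher, adjusted p = 3.06e-05, and adjusted p = 0.413 with an estimated correlation), with medians of 1.9, 0.4 and -0.2 by batch. Of 26 genes of the NF-kB list, 0 passed by edgeR in either adjustment, with 2 at an unadjusted p under 0.05, 1 past by DESeq2 and 0 by limma-voom (camera adjusted p = 0.486, and adjusted p = 0.924 with an estimated correlation). Immediate early genes were higher as a list (camera adjusted p = 2.38e-07, and adjusted p = 0.421 with an estimated correlation), although 0 of 30 passed over all genes by edgeR and 1 adjusted over the list alone; 3 were at an unadjusted p under 0.05, 1 passed by DESeq2 and 1 by limma-voom. Its medians were 1, 0.02 and -0.03 by batch. Type I interferon response genes had positive values in 38 of 38 members with 0 past by edgeR in either adjustment, 5 at an unadjusted p under 0.05 and 0 past by DESeq2 and limma-voom (camera adjusted p = 1.6e-11, and adjusted p = 0.488 with an estimated correlation). The median of this list was 1.04, 0.5 and -0.4 by batch.

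For this comparison 15 genes passed without the batch term, 409 by DESeq2, 116 without batch 1 and 88 without batch 2, and single libraries weighed on it: 97 without trap replicate 3, 137 without trap replicate 1, and 131 and 134 without untreated replicates 5 and 2. With the replicate block 36 passed; of the 25 named genes past the threshold 10 passed again, Metrnl, Cass4, Pdgfa, Itgb3 and Spsb1 among them, and the other 15 had adjusted p from 0.0949 to 0.672. When each library was left out in turn, Maf lost its call in 10 of the fits, Cd36 in 9, Mertk in 8, Il1rl1 in 6, Hdc and Atp2b4 in 5, Pald1 in 3 and Sbno2 in 2. Cma1 lost its call without untreated replicate 6 (adjusted p = 0.0883), Slc18a2 without untreated replicate 4 (0.125) and Tlr4 without trap replicate 3 (0.0664). Mcpt4 and Tpsb2 passed without trap replicate 3 (0.00271 and 0.000425), and Il10 passed without untreated replicate 3 (0.0267) or trap replicate 2 (0.046).

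The direct comparison of the supernatants asked what traps add to mast cell material. Genes of the type I interferon response were higher with trap than with mast cell supernatant as a group, with positive medians in each batch. Camera with a preset correlation of 0.01 placed the list above other genes (adjusted p = 2.52e-33). With the estimated correlation, which was 0.87, camera gave adjusted p = 0.446. Single genes did not pass over all genes. Ifit1, an interferon-induced antiviral gene (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009), averaged 82.9 ± 61.4 CPM with trap supernatant (SD, n = 3), 23.6 ± 15 CPM with mast cell supernatant (n = 5) and 41.5 ± 19.2 CPM untreated (n = 6). Its log2 difference between the supernatants was 1.93 ± 0.51 (adjusted p = 0.897), with 2.01, 2.29 and 1.55 in the 3 batches. Of the 38 measured members 37 had positive values, with a median of 0.603 and medians of 0.77, 0.89 and 0.32 by batch. By edgeR 0 passed over all genes and 20 adjusted over the list alone; 23 were at an unadjusted p under 0.05, 3 passed by DESeq2 and 0 by limma-voom. Examples chosen after their values were seen are Mx2 and Rsad2, both antiviral genes, at 1.79 ± 0.42 and 1.83 ± 0.58, and Irf9, a subunit of the interferon-activated transcription factor, at 0.38 ± 0.09. Ifit and Mx family members share sequence, and reads could be divided among them. Against untreated cells the list was lower with mast cell supernatant by camera (adjusted p = 0.00613, and adjusted p = 0.796 with an estimated correlation; 0.117 with the replicate block, and 0.346 without untreated replicate 3), with 0 of 38 past by edgeR in either adjustment, 6 at an unadjusted p under 0.05, 2 past by DESeq2, 0 by limma-voom, and medians of 0.35, -0.43 and -0.77 by batch.

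**Figure D3:**
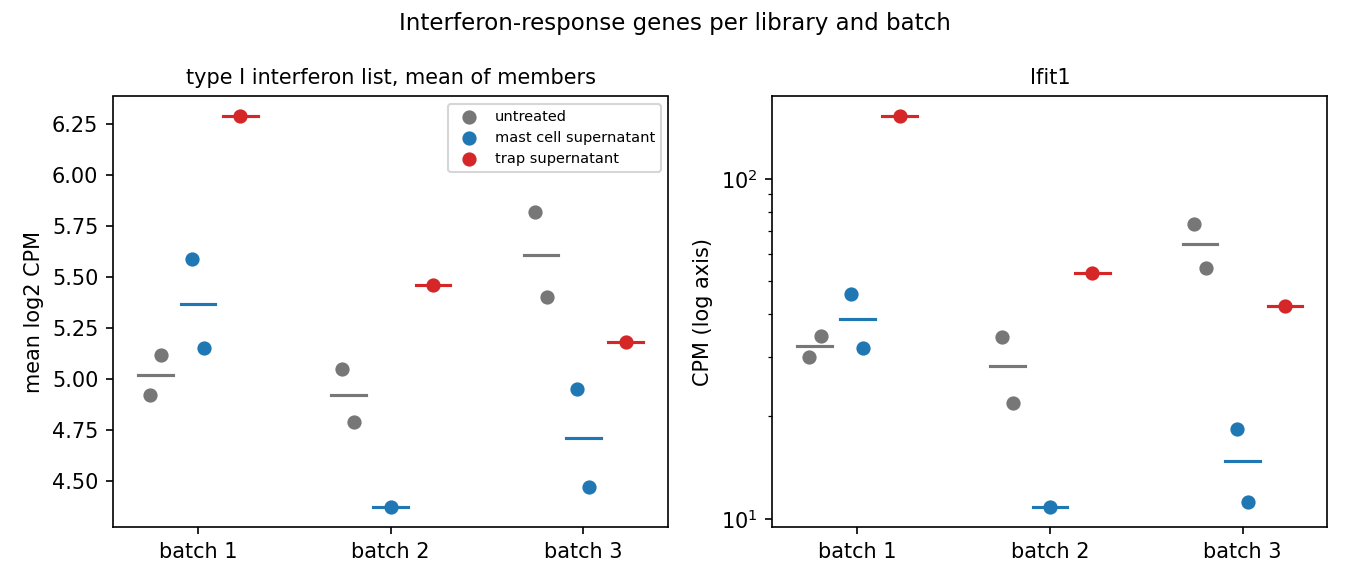
Mean log2 CPM of the 38 measured type I interferon response genes and CPM of Ifit1 (logarithmic axis) for each library (points) by batch, with short bars for the mean of a group in a batch. The trap library lies above the mast cell supernatant libraries of its batch in each of the 3 batches; untreated libraries are higher in batch 3 (Ifit1 at 73.7 and 54.8 CPM) than in batch 1 (29.9 and 34.5 CPM).

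The interferon-gamma and MHC class II list was also higher with trap supernatant (24 measured; 0 past over all genes by edgeR and 5 adjusted over the list alone; 6 at an unadjusted p under 0.05, 2 past by DESeq2 and 0 by limma-voom; camera adjusted p = 6.53e-08, and adjusted p = 0.619 with an estimated correlation), with medians of 0.4, 0.41 and 0.04 by batch and adjusted p = 0.145 without trap replicate 1. Irgm2, an interferon-inducible GTPase gene chosen after its value was seen, stood at 1.11 ± 0.24. Cell cycle genes were lower with trap supernatant (33 measured, 26 negative, median -0.143, and -0.08, -0.15 and -0.16 by batch; 0 past by edgeR in either adjustment, 5 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom; camera adjusted p = 4.98e-07, and adjusted p = 0.446 with an estimated correlation). The mast cell list was higher by camera (adjusted p = 8.4e-09, and adjusted p = 0.619 with an estimated correlation), but its batch medians were -0.03, -0.84 and 2.98, and without trap replicate 3 it was lower (adjusted p = 4.56e-07). The STAT5 and IL-10/STAT3 lists were higher (camera adjusted p = 0.0177 and 0.0265, and adjusted p = 0.619 and 0.866 with an estimated correlation), with 1 and 0 members adjusted over the list alone. Their medians by batch were 0.09, 0.18 and 0.3, and 0.07, 0 and 0.21. Over all genes 0 of 13061 passed by edgeR (smallest adjusted p 0.842), with 569 at an unadjusted p under 0.05 against 653 expected, 11 by DESeq2, all higher with trap supernatant, and 0 by limma-voom.

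When only the 8 treated libraries were fitted, as planned beforehand, 22 genes passed by edgeR and all 22 were higher with trap supernatant. Mx2, Rsad2 and Irgm2 were among them, with log2 differences of 1.82 ± 0.13, 1.81 ± 0.12 and 1.11 ± 0.14 (adjusted p = 3.64e-05, 0.000822 and 0.0152). In this fit, 6 of the 38 type I interferon genes passed. The list tests in these libraries were not planned and were added after seeing the data. They gave 26 members past when adjusted over the list alone (camera adjusted p = 1.26e-62, and adjusted p = 0.257 with an estimated correlation).

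Genes past the threshold with both supernatants changed in the same direction. The type I interferon list, without single genes past by edgeR, had pooled medians of 0.398 with trap and -0.321 with mast cell supernatant. By batch its medians were 1.04, 0.5 and -0.4 with trap and 0.35, -0.43 and -0.77 with mast cell supernatant. The signs thus differed in batch 2 only, and neither direction passed camera with an estimated correlation (adjusted p = 0.488 and 0.796). Of the 224 genes past the threshold with trap supernatant, 206 also passed with mast cell supernatant, 108 higher in both, 98 lower in both and 0 opposite; independent lists would share 2.6 and 2.72. The 18 other trap genes all had the same sign with mast cell supernatant, and 412 of the 419 genes past with mast cell supernatant alone had the same sign with trap supernatant; these differences were tested only in the direct comparison above. Across 13061 genes, which are not independent replicates, log2 fold changes correlated at r = 0.909, against a mean of 0.354 and a highest value of 0.426 in 100 simulations of unchanged groups on the same controls. Their covariance was 0.283 against a simulated 0.0172, a difference of 0.266. The simulated libraries varied independently around their batch means, so anything that treated libraries of a batch share is missing from the simulated values. Among the 11865 genes at 1 CPM or more in untreated cells, 62 were higher in both and 98 lower in both. There r was 0.698 (simulated 0.364) and the covariance 0.0409 (simulated 0.00969). With the controls split between the comparisons, 60 and 25 of all genes were shared, all in the same direction, and r was 0.848 and 0.85. Among genes at 1 CPM or more, 10 were higher and 22 lower in both in 1 split, and 2 and 8 in the other. There r was 0.553 and 0.548.

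**Figure D4:**
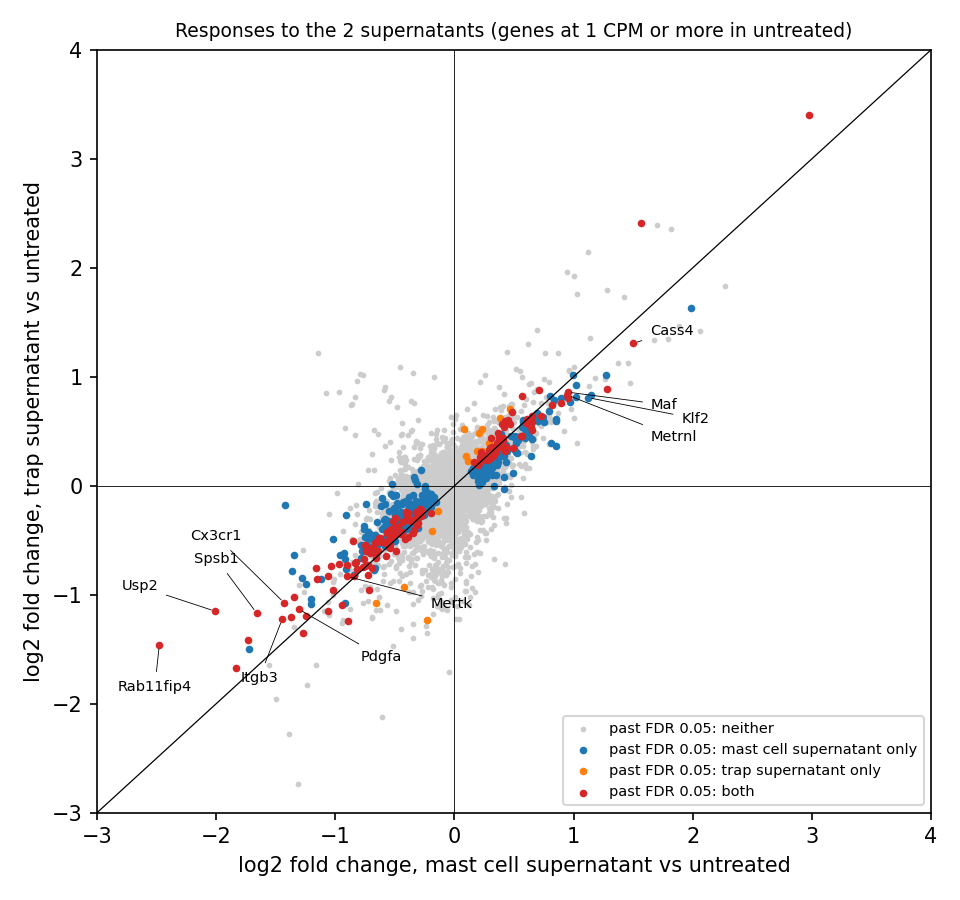
Log2 fold change against untreated with mast cell supernatant (horizontal) and with trap supernatant (vertical) for genes at 1 CPM or more in untreated cells (11864 points; 1 gene lies outside the axes), coloured by which comparison passed, with the line of equal change. Genes past in both lie in the quadrants of equal sign.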

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

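All tests in this part were chosen after their results were seen, except the counts of other splits of the libraries.

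Of 122 groups of values tested for a library far from the others, 7 held one, and chance gives about 6.1. Mast cell supernatant replicate 2, the single library of that group in batch 2, held 5 of the 7. Its log2 CPM was 4.785 for Hdc (others 2.246 to 2.797). It was lower than the others for Metrnl (8.536; 8.923 to 9.08), Ciita (0.05351; 1.608 to 2.141), Pparg (5.79; 6.405 to 6.597) and Pf4 (7.109; 7.918 to 8.199). Cma1 stood at -2.991 in untreated replicate 6 and Slc18a2 at -2.676 in untreated replicate 4, with -3.924 in each of the other untreated libraries, which had 0 counts.

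Mast cell transcripts in the treated libraries may be RNA or whole cells carried over with the supernatants. Across the 8 treated libraries the level of 11 such transcripts varied with an SD of 2.13 (log2), while single transcripts varied around this common level with a median SD of 0.48 and at most 1.04, as a shared source would give. Transcription in the macrophages stays open: the 4 protease transcripts were above every untreated library in 8 of 8 treated libraries, and each of these received mast cell material. For most of the rises past the threshold in genes that untreated macrophages express, the tables argue against the same source with trap supernatant only. These genes passed a model that favours changes alike in all batches, so nothing is said of genes that did not pass. Among them the gain in batch 1 was a median of 86.2% of that in batch 3 over 71 such genes (lower quartile 60.5%), against 3.44% for the mast cell transcripts (highest 6.51%). With mast cell supernatant this was 95.1% over 228 genes (lower quartile 51.5%) against 30.1% (highest 49.9%), too close to exclude it.

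The response to mast cell supernatant differed between batches 1 and 3 for 1467 genes by a test of the difference itself. Of these, 1027 had a larger value in batch 1 and 440 a smaller one. The spread in this test came only from libraries of the same batch and group, which may be technical replicates. The count therefore holds for these libraries, and whether the differences would recur in a repeat of each batch was not tested. For trap supernatant 568 genes differed, but it has a single library in each batch, whose spread is assumed to be like that of the other groups. The larger values in batch 1 included 23 of 26 NF-kB genes and 11 of 16 chemokines. Less mast cell RNA in batch 3 is argued against, since its mast cell supernatant libraries held more, by 1.5 on the log2 scale (4.17 in batch 1 and 5.68 in batch 3), and so is an exchange of treated and untreated libraries, since the highest untreated level of the 4 protease transcripts in batch 3 was 0.0662% of the lowest treated one. Whether untreated macrophages of batch 3 were already active cannot be decided here. In the genes with larger values in batch 1, the untreated difference had a median of 26.1% of the difference in response. These genes were chosen by a difference that itself contains the untreated levels, so a positive median follows from the choice. What differed between batches in the cells or the supernatants is not given in the sources used here and stays open.

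For the interferon genes that stood higher with trap than with mast cell supernatant, the level of mast cell RNA was tried as a covariate. The median log2 difference over the list was then 0.73, against 0.59 without it, and 38 of 38 members were positive. Each batch has a single trap library, no error was computed and the members move together (estimated correlation 0.87), so this fit cannot decide. By batch the medians were 0.77, 0.89 and 0.32 for this list and -0.03, -0.84 and 2.98 for the mast cell list. In batches 1 and 2 the interferon genes were thus higher without more mast cell RNA, on a single trap library each. An effect of trap supernatant itself is a candidate explanation, with a positive median in 3 of 3 batches. Of the 18 arrangements of treated libraries within batches, 1 gave a mean difference as large as the real 0.8, the real one itself, and the highest other gave 0.68. So few arrangements cannot give a share under 0.05 (the smallest is 0.056), and differences between supernatant preparations cannot be told apart from the trap.

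Chance as the source of the calls was tested by other splits of the libraries. For trap supernatant against untreated, 1 of 84 splits, the real one, gave as many genes as 224, and the highest other gave 29. This argues against a chance arrangement of single libraries for this count. Libraries of the same batch and group were more alike than others and may be technical replicates. The splits therefore cannot exclude chance with batches as the units. At an unadjusted p under 0.05 the real split gave 1666 genes and the highest other 2007. For mast cell supernatant against untreated, the real split was the 1 of 100 drawn that gave as many as 625. The highest other gave 532, and the other splits with the real batch makeup gave at most 0. For this count too the values argue against a chance arrangement of single libraries, with the same limit. At an unadjusted p under 0.05 the real split gave 2501 genes and the highest other 2607. The split with 532 had untreated replicates 2, 3, 5 and 6 and mast cell supernatant replicate 2 on one side. It thus parts treated from untreated libraries in batch 3 and sets batches 1 and 2 against each other, so it holds part of the real contrast. For trap against mast cell supernatant, the real count was 0 by edgeR (569 genes at an unadjusted p under 0.05, 11 past by DESeq2 and 0 by limma-voom), so 56 of 56 splits had to give as many, and this count says nothing on chance. The highest other, 507, set the 3 treated libraries of batch 1 against those of the other batches, which points to a structure by batch.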

How the results depend on the processing

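The model with 9 group-by-batch means, counts without genes nearly absent from untreated cells, list tests with the replicate block or in the 8 treated libraries, and folds without the library richest in a transcript were chosen after seeing the data; the other alternatives were planned.

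For trap supernatant against untreated, 224 genes became 409 by DESeq2, 15 without the batch term, 849 with 9 means, 116 without batch 1, 88 without batch 2, 70 at 2-fold or more and 84 at a rate of 0.01; leaving out each library gave 97 to 280. For mast cell supernatant against untreated, 625 became 62 without the batch term, 1424 with 9 means, 231 without batch 2, 94 at 2-fold or more and 257 at 0.01; leaving out each library gave 449 to 751. For trap against mast cell supernatant, 0 by edgeR (569 at an unadjusted p under 0.05, 0 by limma-voom) became 11 by DESeq2, 22 with only these groups, 73 with 9 means and 1 without batch 3. Leaving out each library gave 0 to 3. The main model counts responses that differ between batches as spread, and the model with 9 means does not. The count of 0 therefore does not show that the supernatants act alike. With 9 means the spread comes only from libraries of the same batch and group. The cause of the other shifts was not tested.

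With the replicate block, on 9 of the libraries, the counts against untreated became 36 for trap and 84 for mast cell supernatant. The block is the same term as batch there, so these fits differ from the main model in having fewer libraries. The genes shared by both responses, 206, became 60 and 25 with the controls split, where each fit has fewer libraries.

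Lists past camera with a preset correlation, 13, 11 and 6 for the comparisons in the above order, became 0, 0 and 0 with an estimated correlation and 3, 2 and 0 by fry. Those for mast cell supernatant became 7 without the batch term and 5 with the replicate block. With trap supernatant against untreated, the estimated correlation was 0.87 for type I interferon, 0.66 for mast cell and 0.49 for immediate early genes. The preset 0.01 lies far below these, which makes the preset adjusted p too small. It was 0.02 for the LXR list and 0.06 for the IL-4/STAT6 list, which were lost too. Whether anything else lowered the counts was not tested. The mast cell list between the supernatants reversed without trap replicate 3 (adjusted p = 4.56e-07), and its adjusted p ran up to 0.000185 and down to 4.43e-29 without mast cell supernatant replicates 5 and 2. Cpa3, between -0.53 and 1.92 on the log2 scale, reversed with it; trap replicate 3 held the most Cpa3.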

Other observations

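The lists in this part were fixed beforehand, and their tests with the replicate block were added after seeing the data. Some stress-response genes rose with mast cell supernatant. Of 25 genes of the unfolded protein and ATF4 list 4 rose and 0 fell, also adjusted over the list alone, among them Ddit3 (0.4 ± 0.09) and Sesn2 (0.36 ± 0.06) (camera, higher, adjusted p = 0.00324, and adjusted p = 0.524 with an estimated correlation; medians of 0.18, 0.05 and 0.07 by batch). Ddit3 lost its call in 3 of the fits that leave out a library. With trap supernatant 1 rose, Hspa5 (0.35 ± 0.08), a call lost in 12 of the fits that leave out a library, and 5 adjusted over the list alone (camera adjusted p = 0.114, and adjusted p = 0.787 with an estimated correlation). Of 17 heat shock genes 2 rose with mast cell supernatant (4 adjusted over the list alone; camera, higher, adjusted p = 0.00151, and adjusted p = 0.524 with an estimated correlation; medians of 0.23, 0.06 and 0.09 by batch). With trap supernatant 0 passed by edgeR and 3 rose adjusted over the list alone (5 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom; camera, higher, adjusted p = 0.00445, and adjusted p = 0.415 with an estimated correlation; medians of 0.23, 0 and 0.09 by batch).

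Of 29 glycolysis and hypoxia genes 3 rose and 3 fell with mast cell supernatant, Hk2, the hexokinase 2 gene, by -0.78 ± 0.15 (6 and 5 adjusted over the list alone; camera adjusted p = 0.209, and adjusted p = 0.796 with an estimated correlation). With trap supernatant camera gave adjusted p = 0.69, and adjusted p = 0.924 with an estimated correlation. The cholesterol synthesis list of 24 was higher by camera with mast cell (adjusted p = 0.0231) and trap supernatant (0.00446), and adjusted p = 0.796 and 0.764 with an estimated correlation. With each supernatant 0 of its genes passed by edgeR in either adjustment, 0 were at an unadjusted p under 0.05, and 0 passed by DESeq2 and limma-voom; 5 were negative with mast cell and 2 with trap supernatant. Its medians by batch were 0.04, 0.04 and 0.26 with mast cell and -0.07, 0.22 and 0.33 with trap supernatant. Of 24 NRF2 genes, Gsr, the glutathione reductase gene, rose with mast cell supernatant (0.26 ± 0.05; 3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0617, and adjusted p = 0.602 with an estimated correlation), and camera gave 0.468 with trap supernatant. For 29 lysosome genes camera gave 0.794 and 0.486, and for 12 mitochondrially encoded mRNAs 0.562 and 0.898, with mast cell and trap supernatant.

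Among immune lists, Clec10a (0.57 ± 0.14) and Pparg (0.41 ± 0.08), markers of alternative activation, rose with mast cell supernatant and 0 of 20 fell in the IL-4/STAT6 list (camera adjusted p = 0.0644, and adjusted p = 0.524 with an estimated correlation); Clec10a lost its call in 5 of the fits that leave out a library. With trap supernatant the list was higher by camera (adjusted p = 0.00997, and adjusted p = 0.413 with an estimated correlation). There 0 passed by edgeR, 2 adjusted over the list alone, 3 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. The medians by batch were 0.48, 0.09 and -0.05. Ciita, the MHC class II activator gene, fell with mast cell supernatant (-0.84 ± 0.19) in the interferon-gamma list of 24 (camera adjusted p = 0.0673, and adjusted p = 0.796 with an estimated correlation), and lost its call without mast cell supernatant replicate 1 (0.05). With trap supernatant that list was higher by camera (0.0145, and adjusted p = 0.787 with an estimated correlation). Here 0 passed by edgeR in either adjustment, 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom, with medians of 0.67, 0.13 and -0.28 by batch. The STAT5 list of 17 had 0 rises and 1 fall with mast cell supernatant (camera adjusted p = 0.599), and was higher by camera with trap supernatant (0.00997, and adjusted p = 0.413 with an estimated correlation). There 0 passed by edgeR, 1 adjusted over the list alone, 3 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom, with medians of 0.4, 0.04 and 0 by batch. Fkbp5 and Klf9, glucocorticoid targets, fell with mast cell supernatant by 0.57 ± 0.11 and 0.74 ± 0.13, and Fkbp5 fell with trap supernatant by 0.64 ± 0.12 (16 measured; adjusted over the list alone, 4 rose and 2 fell with mast cell supernatant, 0 and 2 with trap; camera 0.254 and 0.664, and adjusted p = 0.796 and 0.924 with an estimated correlation); the latter call was lost without trap replicate 1 (0.113) or 3 (0.0566). In the inflammasome and cell death list of 23, 1 rose with each supernatant; adjusted over the list alone, 3 rose and 5 fell with mast cell supernatant and 1 rose with trap (camera 0.713 and 0.486, and adjusted p = 0.877 and 0.792 with an estimated correlation).

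Cell cycle genes were higher by camera with mast cell supernatant (33 measured; adjusted p = 0.0231, and adjusted p = 0.602 with an estimated correlation; 0.0602 with the replicate block, and 0.0691 without untreated replicate 6). By edgeR 1 passed over all genes and 0 adjusted over the list alone, with 9 at an unadjusted p under 0.05, 3 by DESeq2 and 1 by limma-voom. The medians by batch were 0.01, 0.05 and 0.21, and camera gave 0.264 with trap supernatant. Markers of other cells gave adjusted p by camera, with mast cell and trap supernatant, of 0.562 and 0.486 for the 4 T, B and NK cell markers, 0.82 and 0.907 for the 8 dendritic cell markers and 0.0673 and 0.486 for the 11 stromal and endothelial markers. Neutrophil markers gave 0.885 with mast cell supernatant. With mast cell supernatant the neutrophil and dendritic lists had positive medians (0.071 and 0.044) where camera ranked them lower. Tcf4, in the dendritic list, fell by 0.34 ± 0.07 with mast cell supernatant. The 3 erythroid and megakaryocyte markers were higher by camera (0.0231 and 0.00446, and adjusted p = 0.479 and 0.238 with an estimated correlation). Their medians by batch were 0.26, 0.42 and 0.48 with mast cell and 0.6, 1.02 and 0.28 with trap supernatant. Itga2b, 1 of the 3, was at 6.39 ± 6.47 CPM with trap supernatant and 0.695 ± 0.351 untreated. Its log2 change of 2.87 ± 0.75 did not pass (adjusted p = 0.109) and was 0.66, 3.48 and 3.66 by batch. Pf4 passed at 0.24 ± 0.06 with mast cell supernatant, a call lost in 9 of the fits that leave out a library.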
